A study of Homo sapiens with 5 samples.

How the data were processed

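Polyadenylated RNA of MDA-MB-435 cells, an established human tumour cell line, was compared on 5 spotted cDNA arrays with 2 channels each. Each array held RNA of cells given alpha-TEA, an ether analog of vitamin E, against RNA of cells given the ethanol vehicle, for 12 h. The sample labels give a dose of 40 µM, while the series design text writes the same number with a millimolar unit; the labels were followed. Per the labels, treated RNA carried Cy5 and vehicle RNA Cy3 on arrays 1, 2, 3 and 5, and the dyes were exchanged on array 4. The names of arrays 1, 4 and 5 start with HS9 and those of arrays 2 and 3 with HS11, which was used as a possible batch. Nothing in the labels says that the arrays came from separate cultures, and arrays 4 and 5 may share RNA. P-values of single probes and genes therefore measure the spread between arrays, which may be technical. Those of gene sets at a preset correlation compare a list with the other genes, so they do not measure replication over arrays.

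The deposited values were log2 ratios of the 2 channels of each array, per the series design text, with blanks where a spot had been filtered. The same text states that slides were scanned on an Axon GenePix scanner, quantified in GenePix, and filtered on quality thresholds in the Longhorn Array Database. Background correction, centring within the array and the filter thresholds are not given in the sources used here. The table held 46467 probes, of which 376 had no value on any array and 5819 had a value on every one of the 5 arrays. Measured probes numbered 40454, 37119, 13599, 27490 and 30744 on arrays 1 to 5. Column medians were 1.15, 0.67, 1.14, -0.35 and 1.39, so the values had not been centred. A floor of -16.61 was reached by 4 values on array 2 and 3 values on array 3. Spot intensities were not analysed here, so signal over background, a filter on dim spots and intensity-dependent normalization could not be applied. The stated precision reflects the spread between arrays and does not cover error from these sources.

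The scale of the table is log base 2, but its direction remained unknown. The design text describes treatment over control. On the 4 arrays with treated RNA in Cy5, the inverse of the antilog was a ratio with 3 decimals for 100, 99.99, 99.99 and 100% of values, counting ratios between 0.3 and 8 and a tolerance of 0.02 thousandths. On array 4 the antilog itself was such a ratio for 100% of values. Array 4 had thus been turned relative to the others, provided the rounded ratio has the same channel order on every array. That order is stated in none of the sources used here, and it decides whether all columns are treated over vehicle or vehicle over treated. Values are therefore given as lying on the negative or the positive side of the deposited ratio.

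Each array was centred by subtracting its median over all probes. A rule fixed before the data were examined decided the use of array 4: its correlation over probes with the mean of the other 4 had to reach 0.1 for use as deposited, or -0.1 for use with the sign turned. Pearson's r was 0.042 (Spearman's rho -0.0081), so array 4 was left out and arrays 1, 2, 3 and 5 were fitted. The outcome depends on the level at which the rule is applied: over 7801 genes measured on both sides, r was 0.187 (rho 0.125), a value computed only afterwards, and the rule for probes was kept. Because the 4 fitted arrays share one dye orientation, an effect of the treatment and a gene-specific effect of the dyes cannot be separated in the fit.

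Probe names came from the platform annotation. In all, 22013 probes had 1 gene symbol, 843 had several and 23611 had none given. Of the probes with 1 symbol, 21930 were matched by gene number to RefSeq genes of GRCh38.p14, which was used for names only since the sources name no build. The value of a gene was the mean over its probes with exactly 1 symbol, which gave 13368 genes. Features with a value on at least 3 of the 4 fitted arrays entered the test: 26751 probes (8418 on all 4) and 10094 genes (5047 on all 4, 5169 with more than 1 probe).

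The mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, adjusted p under 0.05). Adjusted p-values of genes below are from this fit. The study's criterion of a log2 ratio of 1 in size was counted without a test. Sets of genes were tested with limma's camera at a preset correlation of 0.01 over genes measured on every fitted array, and again with the correlation estimated, for 26 lists fixed before the data were examined, 4 of them markers of cell types. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

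The genes named in the text followed a rule fixed at the same time. It takes genes past the test with a value of the same sign on all 4 fitted arrays, the 12 lowest and the 12 highest means. Where fewer pass, the side is filled by size with genes of the same sign on every array, which are said not to pass. It adds up to 4 members of each list with the smallest p, and PMAIP1, TP73, BBC3, DDIT3, TNFRSF10B, FAS, JUN, MCL1 and BCL2L11. TP73, DDIT3 and JUN had no probe with a single symbol here, and BBC3 and BCL2L11 had a value on 1 and 2 fitted arrays, so none of these was fitted. VMP1, SYTL2 and RELA lie outside the rule and were named after their values had been seen.

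The procedure was tested on 20 simulated sets of the 10094 genes with 200 changed genes each. It called 19.3% of genes changed by a log2 of 1, 70.1% at 1.5, 91.1% at 2 and 96.7% at 2.5, and on average 4.71% of its calls were unchanged genes. Simulated genes varied independently, with normal noise from the fitted model that was alike on every array. These rates therefore do not cover correlated genes, a shared dye effect or an extreme array. A list shifted by -0.5 was found in 20 of 20 sets with the preset correlation and in 0 of 20 with the estimated one. A call that ends with the estimated correlation may thus reflect a lack of power, and does not show that the list is unchanged. Alternatives covered the use of array 4, its averaging with array 5, centring, scaling, the minimum number of arrays, the array name prefix, robust and weighted fits, the median over probes and the omission of each array. A fit without the floor values and a fit of all 5 arrays with a dye term were chosen after seeing the data.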

Results

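The series measured how the transcripts of MDA-MB-435 cells responded to alpha-TEA, an ether analog of vitamin E, at 40 µM for 12 h, relative to the ethanol vehicle. MDA-MB-435 is a human tumour line that was long used as a breast cancer model and that expresses melanocyte genes. All 5 arrays belong to 1 group, since each carries treated and vehicle RNA together. The 4 arrays with treated RNA in Cy5 were fitted, and array 4, with exchanged dyes, was set beside them. The share of the 46467 probes with a value ranged from 29.3% on array 3 to 87.1% on array 1. Among the fitted arrays, the log2 ratios of probes correlated pairwise at r = 0.177 to 0.331, across probes, which are not independent replicates.

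Signed values below are log2 ratios as deposited, after subtraction of the array median. The series design text describes the ratio as treatment over control. The number encoding of the table left this open, so no gene is called higher or lower in treated cells. If the ratio is treated over vehicle, a negative value means less transcript in treated cells. If it is vehicle over treated, every sign is mirrored. Means are given with the SD over arrays.

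Of 10094 genes, 18 changed at an adjusted p under 0.05, 17 of them on the negative side and 1 on the positive side. The lowest mean was that of PMAIP1, which encodes the proapoptotic BCL2 family protein NOXA, at -2.29 ± 0.63 (SD, n = 4; limma adjusted p = 0.038), a 4.90-fold difference. GARS1, the glycyl-tRNA synthetase, followed at -2.24 ± 0.25 (n = 4; limma adjusted p = 0.024). The stress-response transcription factor ATF4 was at -1.92 ± 0.39 (n = 4) and the mitochondrial folate enzyme MTHFD2 at -1.87 ± 0.58 (n = 4). Immediate early genes changed to the same side, with EGR1 at -2.19 ± 0.30 (n = 3) and IER3 at -2.17 ± 0.33 (n = 4).

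Further genes on the negative side were the tyrosine kinase ABL2 (-2.01 ± 0.41), the nucleoporin NUP88 (-1.77 ± 0.48) and the calcineurin regulator RCAN1 (-1.75 ± 0.39). PPP1R15A, a phosphatase subunit that acts on the translation factor eIF2α, was at -1.64 ± 0.35. DPYSL2 was at -1.60 ± 0.24, the translation elongation factor EEF2 at -1.55 ± 0.39, the scaffold protein AHNAK at -1.48 ± 0.31 and the transcription factor KLF4 at -1.44 ± 0.32. VMP1, a membrane protein of autophagy, was at -1.42 ± 0.07, SYTL2 at -1.39 ± 0.26 and the NF-kB subunit RELA at -1.37 ± 0.15. The gap junction gene GJA4, at 1.88 ± 0.60, was the 1 call on the positive side. Each of these genes had n = 4 and the same sign on the 4 arrays. The adjusted p-values of the 18 genes (limma) lay between 0.024 and 0.047. The 2 probes of KLF4 differed, with -1.84 over 4 arrays and 0.45 on 1 array.

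**Figure D1:**
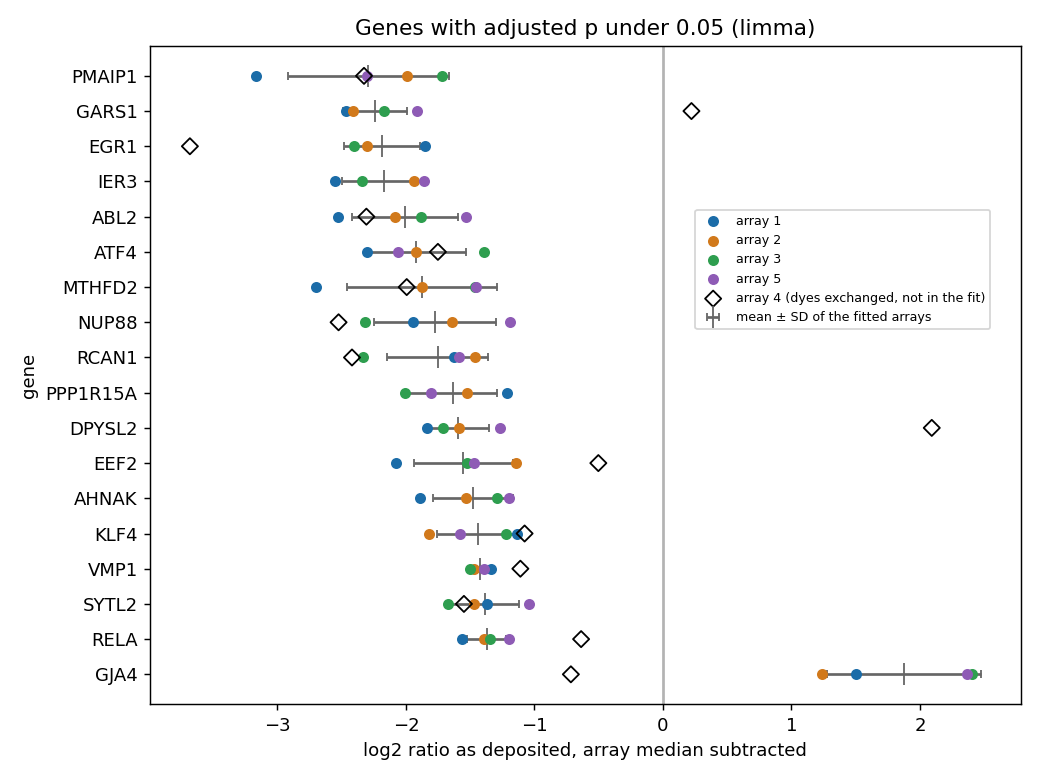
Log2 ratios as deposited, after median subtraction, of the 18 genes past the test; dots are the fitted arrays, bars the mean ± SD, open diamonds array 4 with exchanged dyes. Array 4 lies on the negative side for 12 of the 14 negative genes measured there, while DPYSL2 (2.09), GARS1 (0.22) and GJA4 (-0.72) lie opposite to the fitted arrays.

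Other genes with high means did not pass the test. FAM163A had 2.26 ± 1.33 and HCG4 1.64 ± 0.64 (n = 4; limma adjusted p = 0.10 and 0.060). HCG4 stood at -3.75 on array 4, and its sign turned (-1.06) in a fit of all 5 arrays with a dye term. ARHGEF7 (1.95 ± 2.47) and DNASE1L3 (1.65 ± 2.68) had their size from array 3, where both stood at 5.66. SLC25A42 (1.33 ± 1.10), SNRNP48 (1.26 ± 1.73), ASIC1 (1.23 ± 2.05), IFT122 (1.22 ± 0.56), ITGAM (1.19 ± 1.21), PLGLB1 (1.15 ± 1.95) and TBXAS1 (1.14 ± 0.96) completed this side and did not pass either (n = 4). SNRNP48, ASIC1 and PLGLB1 too had their highest value by far on array 3.

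An unadjusted p under 0.05 was reached by 1530 genes, against 504.7 that chance would give, 1067 on the negative and 463 on the positive side. Over single probes, 10 of 26751 passed (8 negative, 2 positive). Omitting array 1, 2 or 5 left 0 genes past limma's threshold (1035, 1331 and 1143 genes at an unadjusted p under 0.05), and omitting array 3 left 24. With the name prefix as a block 0 genes passed (1648 unadjusted), as within the 2 HS9 arrays (1606) and the 2 HS11 arrays (666). Without median subtraction, which shifts the median of all genes to 1.04, 8446 genes passed, 14 negative and 8432 positive, so the main split of 17 to 1 is relative to the array median.

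The study's own criterion, a mean log2 ratio of 1 in size, was met by 278 genes, 161 on the negative and 117 on the positive side. Of these, 18 also passed the test, 17 negative and 1 positive. All measured arrays gave the same sign for 150 of the negative and 86 of the positive genes. Among the 5047 genes measured on all 4 arrays, 1483 (29.4%) had the same sign on each, 1169 negative and 314 positive. Chance gives 12.5% with evenly split signs. These genes had a median of -0.11 after centring on all probes, and each array's own share of negative genes gives 15.2% by chance, 661 negative and 107 positive. Without median subtraction 5472 genes met the criterion, 5 negative and 5467 positive. The count was 258 to 450 with 1 array omitted, 412 and 477 within the HS9 and HS11 arrays, 456 with 2 arrays required and 154 with all 4, 171 with array 4 added in turned sign and 148 with a dye term.

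Genes of the amino acid response, which cells use when amino acids run short, lay together on the negative side. Of 22 measured members 20 had negative means, with a median of -0.87; 2 passed the test over all genes and 14 adjusted over the list alone. Next to GARS1 and MTHFD2, the asparagine synthetase ASNS had -1.42 ± 0.38 (n = 4) and the stress protein SESN2 -1.82 ± 0.46 (n = 3), which did not pass over all genes (limma adjusted p = 0.058 and 0.060). The list passed as a set over the 12 members measured on all 4 arrays, which leaves out SESN2 (limma camera adjusted p = 5.9e-06). Here and below, camera covers only members measured on all 4 arrays, while counts and medians cover all measured members. With an estimated correlation the call was lost (limma camera adjusted p = 0.54 with an estimated correlation). That test found a list shifted by -0.5 in 0 of 20 simulated sets. In the simulation only the amino acid response was shifted, by less than its observed mean of -0.86, and members varied independently. It covers neither the other lists nor members that vary together. Whether the losses, here and for the lists below, reflect low power or members that vary together therefore stays undecided. The call was also lost with array 4 added in turned sign (limma camera adjusted p = 0.43).

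The unfolded protein response list, chaperones and signalling genes of the endoplasmic reticulum, gave a similar picture. Negative means were found for 17 of 19 measured members (median -0.42). ATF4 and PPP1R15A passed over all genes, and 9 negative and 1 positive member adjusted over the list alone. ATF3, at -1.31 ± 0.42, and the disulfide isomerase PDIA4, at -0.96 ± 0.28 (both n = 4), did not pass over all genes. As a set the list passed, over 14 members (limma camera adjusted p = 5.5e-05). The call ended with an estimated correlation (adjusted p = 0.54 with an estimated correlation) and with array 4 added in turned sign (adjusted p = 0.061).

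Immediate early genes of the JNK and AP-1 pathway had negative means for 16 of 19 measured members (median -0.76). EGR1, IER3 and KLF4 passed over all genes, and 11 members adjusted over the list alone. FOS had -1.92 ± 0.81 (n = 4; limma adjusted p = 0.060) and stood at 0.06 on array 4. Over 15 members the list passed as a set (limma camera adjusted p = 3.8e-06). The call ended with an estimated correlation (limma camera adjusted p = 0.28 with an estimated correlation). ATF3 belongs to this list and to the unfolded protein response list.

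Cytosolic ribosomal proteins also passed as a set on the negative side, over 20 members and by a smaller size (limma camera adjusted p = 0.0063). Of 24 measured members 20 had negative means, with a median of -0.33, 0 passed over all genes and 4 adjusted over the list alone. RPL6 had -0.94 ± 0.25 and RPS6 -1.07 ± 0.44 (n = 4). On array 4 RPL6 stood at 0.17 and RPS6 at 0.22, while 14 of 16 members measured there were negative. With a dye term they were at -0.39 and -0.42. The call ended with an estimated correlation (adjusted p = 0.54 with an estimated correlation), without median subtraction (adjusted p = 0.14), without array 5 (adjusted p = 0.056) and with array 4 added in turned sign (adjusted p = 0.061). Transcripts of this family resemble one another and their pseudogenes, which cDNA probes may not tell apart.

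**Figure D2:**
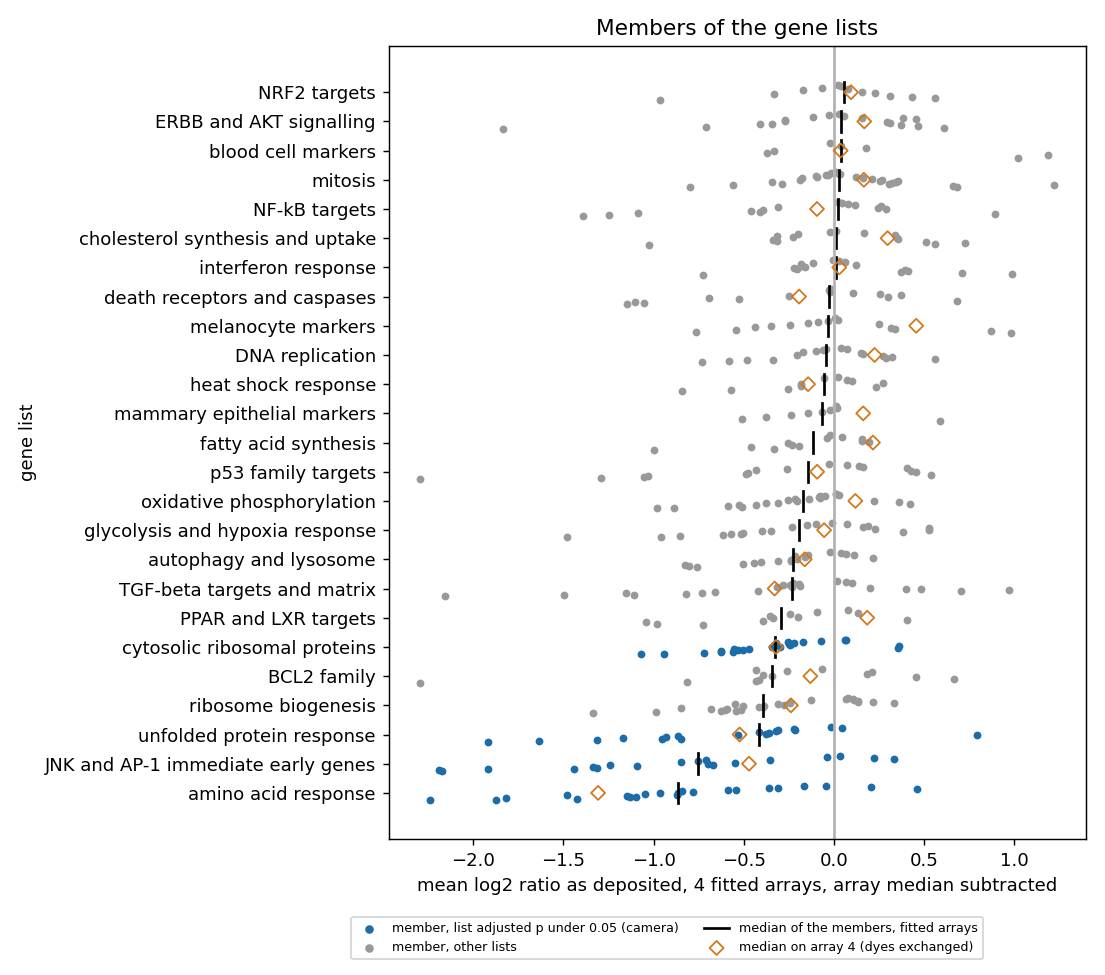
Mean log2 ratio of each measured member of 25 gene lists over the fitted arrays (dots, blue where the list passed camera with the preset correlation), the median of the members (black bar) and the median on array 4 (orange diamond). The amino acid response has the lowest median, -0.87, and -1.31 on array 4.

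Within the 2 HS9 arrays, camera gave adjusted p-values of 0.00097 for the amino acid response, 0.0011 for the unfolded protein response, 0.00035 for the immediate early genes and 0.0047 for ribosomal proteins. Within the 2 HS11 arrays these were 3.9e-09, 0.0011, 2.4e-08 and 0.036. As a block, the prefix gave 3.3e-05, 0.00016, 1.7e-05 and 0.010 (all limma camera, preset correlation). Such p-values compare members with other genes, so small ones from 2 arrays do not measure replication over arrays. With an estimated correlation all 4 calls ended in each of these fits (adjusted p = 0.77 within HS9, 0.75 within HS11 and 0.55 with the block, each with an estimated correlation).

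Genes of cell death were examined since the compound belongs to a class that kills tumour cells. Among p53 family targets 9 of 16 measured members had negative means (median -0.14), 1 passed over all genes, PMAIP1, and 4 adjusted over the list alone. The nuclease gene AEN had -1.29 ± 0.49 (n = 4), the death receptor TNFRSF10B -1.05 ± 0.18 (n = 3) and the cell cycle inhibitor CDKN1A -1.03 ± 0.56 (n = 4), which did not pass. The BCL2 family had 9 of 13 members on the negative side (median -0.34), with PMAIP1 past the test over all genes and over the list alone, and MCL1 at -0.81 ± 0.60 (n = 3), which did not pass. Among death receptors and caspases, 9 of 14 members were negative (median -0.03), 0 passed over all genes and 3 adjusted over the list alone. FADD had -1.14 ± 0.29 (n = 3), BIRC2 -1.10 ± 0.59 (n = 4) and FAS -0.03 ± 0.63 (n = 3). As sets these lists did not pass, over 9, 5 and 7 members measured on all 4 arrays (limma camera adjusted p = 0.18, 0.18 and 0.27).

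Lipid genes did not pass as sets, over 7 cholesterol, 5 fatty acid and 8 PPAR and LXR genes measured on all 4 arrays. The cholesterol list had 7 negative and 8 positive members (median 0.01; limma camera adjusted p = 0.15), with ACAT2 at -1.02 ± 0.41 (n = 3), MSMO1 at 0.56 ± 0.27 and HMGCS1 at 0.51 ± 0.61 (n = 4). Fatty acid synthesis had 8 of 12 members negative (median -0.12; limma camera adjusted p = 0.75), and SREBF1, at -0.999 ± 0.264 (n = 3), was its 1 member past the list alone. PPAR and LXR targets had 9 of 12 members negative (median -0.29; limma camera adjusted p = 0.13) and 3 past the list alone. Their members ANGPTL4 (-0.72 ± 0.09), PLIN2 (-0.98 ± 0.54) and ABCA1 (-1.04 ± 0.78) did not pass over all genes (n = 4). On array 4 SREBF1 stood at 1.32 and ANGPTL4 at 1.02, and with a dye term their signs turned (0.16 and 0.15). ACAT2 stood at 0.82 on array 4 and at -0.10 with a dye term.

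Among stress and growth lists, NRF2 targets had 4 of 12 members negative (median 0.06; limma camera adjusted p = 0.26), with SLC7A11 at -0.96 ± 0.71 (n = 3). The heat shock response had 6 of 11 negative (median -0.05; limma camera adjusted p = 0.33), with DNAJB1 at -0.84 ± 0.75 (n = 4). DNA replication had 9 of 17 negative (median -0.04, adjusted p = 0.62 by limma camera), with RFC4 at -0.73 ± 0.30 and CDC6 at -0.58 ± 0.34 (n = 4). Mitosis had 11 of 26 negative (median 0.03; limma camera adjusted p = 0.18), with KIF2C at -0.80 ± 0.20 (n = 4) and BIRC5 at 0.68 ± 0.44 (n = 3). Ribosome biogenesis had 18 of 26 negative (median -0.39; limma camera adjusted p = 0.14), and ODC1, at -1.34 ± 0.42 (n = 4), passed over the list alone. None of the members of these 5 lists passed over all genes.

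Oxidative phosphorylation had 16 of 22 members negative (median -0.17, limma camera adjusted p = 0.18), with NDUFA9 at -0.98 ± 0.20 and NDUFV1 at -0.89 ± 0.23 (n = 4). NDUFV1 stood at 0.81 on array 4 and at -0.04 with a dye term, while NDUFA9 had no value on array 4. Glycolysis and hypoxia genes had 13 of 20 negative (median -0.19; limma camera adjusted p = 0.098), with the growth factor VEGFA at -1.48 ± 0.60 (n = 3) and the glucose transporter SLC2A3 at -0.96 ± 0.37 (n = 4). NF-kB targets had 7 of 15 negative and a median of 0.02, with NFKB2 at -1.39 ± 0.48 and NFKBIA at -1.25 ± 0.47 (n = 4). Camera tested only 5 of the 15, those measured on all 4 arrays, and placed them on the negative side (limma camera adjusted p = 0.13). The interferon response had 8 negative and 8 positive members (median 0.01; limma camera adjusted p = 0.27), with IFITM3 at -0.72 ± 0.20 and RSAD2 at 0.99 ± 0.77 (n = 4). In each of oxidative phosphorylation, glycolysis and NF-kB targets 2 members passed over the list alone, and 0 over all genes in these 4 lists.

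TGF-beta targets and matrix genes had 15 of 23 members negative (median -0.23; limma camera adjusted p = 0.25). The secreted proteins CCN1 (-2.16 ± 0.99, n = 4), CCN2 (-1.49 ± 0.47, n = 3) and THBS1 (-1.11 ± 0.39, n = 4) did not pass over all genes (limma adjusted p = 0.062, 0.083 and 0.083) and were among 4 past the list alone. The 4 probes of THBS1 disagreed, with means between -2.12 and 0.73. Autophagy and lysosome genes had 14 of 18 negative (median -0.23, limma camera adjusted p = 0.087), with CTSB at -0.76 ± 0.21, MAP1LC3B at -0.80 ± 0.34 and WIPI1 at -0.83 ± 0.37 (n = 4) past the list alone. Probes of MAP1LC3B disagreed, with -1.64 and -0.20 over 4 arrays and 0.61 on 1 array. In the ERBB and AKT list 8 of 18 were negative (median 0.04; limma camera adjusted p = 0.25), and EGFR, at -1.83 ± 0.71 (n = 4; limma adjusted p = 0.060), passed over the list alone. The mean of the 18 members, -0.05, lay on the negative side, while camera, which tested 12 of them, placed the set on the positive side. None of the members of these 3 lists passed over all genes.

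Markers of cell types did not pass as sets, over 8 melanocyte, 3 mammary epithelial and 3 blood cell markers measured on all 4 arrays. Melanocyte markers had 8 of 15 members negative (median -0.03; limma camera adjusted p = 0.17), with MITF at 0.98 ± 0.61 (n = 4) and MC1R at -0.76 ± 0.21 (n = 3). Mammary epithelial markers had 6 of 9 negative (median -0.06; limma camera adjusted p = 0.75), with KRT19 at 0.59 ± 0.15 (n = 3). For both lists camera placed the members it tested on the positive side, against the sign of the median of all measured members. Blood cell markers had 3 of 7 negative (median 0.04; limma camera adjusted p = 0.67), and CD14, at 1.02 ± 0.15 (n = 3), passed over the list alone. Of the fibroblast markers 1, FAP, was measured (0.49 ± 0.41, n = 3), so that list was not tested.

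Array 4, with treated RNA in Cy3, shows which values stay on their side when the dyes are exchanged, provided that its column was turned. Of the 17 genes called on the negative side 14 were measured there, and 12 of them were negative, among them PMAIP1 (-2.33), EGR1 (-3.68), ATF4 (-1.75) and MTHFD2 (-1.99). GARS1 (0.22), DPYSL2 (2.09) and GJA4 (-0.72) lay on the other side, and in a fit of all 5 arrays with a dye term the sign of DPYSL2 turned (0.25). Over all probes array 4 correlated with the mean of the other arrays at r = 0.042, and with array 3 alone at r = 0.182, as high as the lowest pairs of fitted arrays. Added as deposited, it gave 54 genes, all negative, 15 of them shared with the 18. Added with the sign turned, it left 2 genes.

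**Figure D3:**
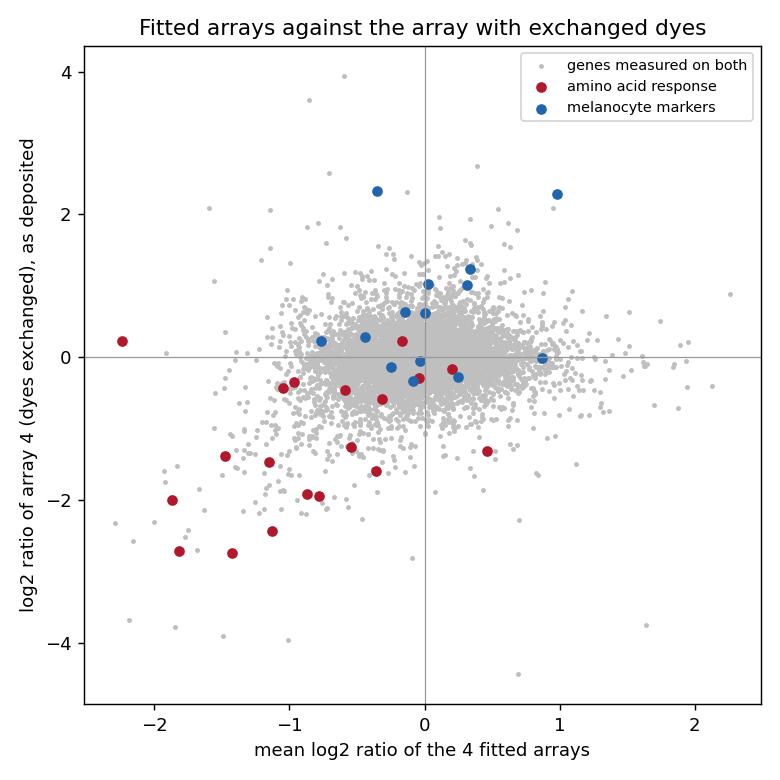
Log2 ratio of each gene on array 4 (dyes exchanged) against its mean over the 4 fitted arrays, both as deposited after median subtraction, for 7801 genes (grey), with members of the amino acid response (red) and melanocyte markers (blue). Across genes, which are not independent replicates, Pearson's r was 0.187, and 17 of 19 members of the amino acid response were negative on array 4.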

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

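All tests in this part were chosen after the results had been seen, except the test of other ways of turning the arrays. The percentile limits for gene lists on array 4 were also set after the percentiles had been seen.

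Of 64 groups of arrays, 9 had 1 array far from the others by Dixon's gap, and array 3, with the fewest measured probes, was the far one in 7. Chance gives about 1 in 20, a rate that does not apply to 11 genes named for the size of their mean alone, which favours genes raised by 1 extreme array. These held 5 of the 9, all on array 3, and the other 53 groups held 4. ARHGEF7 stood at 5.66 on array 3 against 0.54 to 0.88 on the others, and DNASE1L3 at 5.66 against 0.18 to 0.44. On the same array SNRNP48 stood at 3.83 against 0.24 to 0.71, ASIC1 at 4.31 against 0.19 to 0.22, and PLGLB1 at 4.07 against 0.01 to 0.26. DNAJB1 had -1.96 on array 3 against -0.49 to -0.45, and RSAD2 had 2.13 there against 0.45 to 0.71. RPS6 had -0.41 on array 2 against -1.37 to -1.23, and MAP1LC3B had -0.30 on array 5 against -0.99 to -0.96. The probes of MAP1LC3B disagreed, with means of -1.64 and -0.20 over 4 arrays and 0.61 on 1 array. That last probe entered the gene value on array 5 alone.

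Array 4 was outside the main comparison and was examined by itself. The median of each of 25 lists was set among 10000 random lists of the same size from genes of that array, not matched on expression, which the ratios do not give. This describes 1 array. Outside the central 95% of the random medians lay 11 lists, where 1.25 are expected by chance if the members of a list vary independently. Members that vary together would raise that expectation. Limits of 1 and 99% left 10, without fatty acid synthesis. On the negative side were the amino acid response (-1.31), the unfolded protein response (-0.52), the immediate early genes (-0.47), TGF-beta targets (-0.33), ribosomal proteins (-0.32) and ribosome biogenesis (-0.24). Among these, the amino acid response, the unfolded protein response, the immediate early genes and ribosomal proteins had also passed on the fitted arrays. They lay on the same side there, with medians of -0.87, -0.42, -0.76 and -0.33. On the positive side were melanocyte markers (0.46), cholesterol synthesis (0.30), DNA replication (0.23), fatty acid synthesis (0.22) and mitosis (0.17).

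The first pattern is that 17 of 18 called genes lay on the negative side of arrays that share a dye orientation, which a gene-specific dye effect could produce. It would put these genes at or above 0 on array 4 if that column was turned. Their median there was -1.65 (95% bootstrap interval -2.33 to -0.64), with 12 of 14 negative, which argues against a dye effect as the whole cause for most of them. GARS1, DPYSL2 and GJA4 lay on the other side there, and a single array does not exclude it. Turning the arrays in the 8 possible ways gave as many genes 1 time, the real one with 18 and the highest other with 0, and 8 ways are too few for a share under 0.05.

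The second pattern is the low correlation of array 4 with arrays 1, 2 and 5 (r = 0.0155, 0.00748 and 0.0616 over probes). It was less marked with array 3 (r = 0.182), which correlated with the other fitted arrays at r = 0.207 to 0.266. Independent noise on array 4 would leave the covariance unchanged. The mean covariance among the 4 arrays exceeded that with array 4 by 0.0928 (95% bootstrap interval over probes 0.0860 to 0.1004). On the 5818 probes measured on every array the gap was 0.0789 (0.0665 to 0.0921). These intervals resample probes and do not measure the spread between arrays. Arrays 1, 2 and 5 had covariances of 0.0020 to 0.0188 with array 4, below the lowest pair of fitted arrays (0.0761). For these pairs this argues against noise alone. Compression of all values of array 4 by 1 factor would close the gap under equal scaling. The 0.0548 (0.0460 to 0.0627) that remained argues against it, within the limit of an interval over probes. Compression of the signal alone stays open, since the amino acid response, at -1.31 on array 4, was the lowest list there. That list was picked after this was seen. A gene-specific dye effect shared by the arrays stays open too. It would need a variance of 0.0464 (0.0430 to 0.0502), or 0.0274 (0.0230 to 0.0313) after equal scaling. That variance is computed from the same gap and gives it no support. If shared by all 4, the effect would lower the pair with array 3 too. The covariance of arrays 3 and 4 was 0.0992, against 0.131 to 0.157 for array 3 with the other fitted arrays. That pair was thus lower as well, though by less than the pairs with arrays 1, 2 and 5. It lay above the pairs of arrays 1 and 2 (0.0896) and of arrays 2 and 5 (0.0761). A different RNA sample on array 4 was not tested.

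The third pattern is that genes of stress responses lay on the negative side of a ratio described as treatment over control. A candidate explanation is that the deposited ratio is vehicle over treated. On each array with treated RNA in Cy5 at least 99.99% of inverse antilogs were ratios with 3 decimals, as if a Cy5 over Cy3 ratio had been inverted. No source used here states the channel order of that ratio, so the directions cannot be told apart, and a biological decrease stays open and untested.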

How the results depend on the processing

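The fit without floor values and the fit with a dye term were chosen after seeing the data. The cause of a change was not tested unless said.

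Counts are for probes, genes and genes of 2-fold size, against 10, 18 and 278. Adding array 4 as deposited gave 45, 54 and 224, and in turned sign 0, 2 and 171. No centring gave 19297, 8446 and 5472, since it shifts the arrays to the positive side (median of all genes 1.04). Equal scaling gave 0, 45 and 287. Requiring all 4 arrays gave 323, 101 and 154 with fewer features tested, and 2 arrays gave 0, 2 and 456. The prefix as a block gave 1, 0 and 304, HS9 arrays alone 0, 0 and 412, and HS11 arrays alone 0, 0 and 477, with fewer arrays in the last 2. Array weights gave 21, 62 and 241. The dye term gave 0, 12 and 148, with 6 genes shared. Where 0 passed (limma), an unadjusted p under 0.05 held for 1149 to 4998 probes and 666 to 1648 genes. Omitting 1 array at a time gave 0 to 3 probes, 0 to 24 genes and 258 to 450 genes of 2-fold size; 0 genes passed without array 1, 2 or 5. Averaging arrays 4 and 5, the robust fit, the median over probes and the removal of floor values kept the counts run within 1.5 times. With arrays 4 and 5 averaged, however, only 12 of the 16 genes that passed were among the 18.

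For array 4, r over probes was 0.018 to 0.062 when arrays were omitted, scaled or left uncentred, or floor values removed; over genes it was 0.187, past the bound of 0.1. With the dye term signs turned for DPYSL2 (0.25), HCG4 (-1.06), SREBF1 (0.16) and ANGPTL4 (0.15). Without centring they turned for 24 named genes, FAS (1.04) among them, and FAS, near 0, turned in 4 further alternatives. With the preset correlation, which all 19 alternatives share, the immediate early genes kept their set call (highest adjusted p = 0.047, limma camera), but not with an estimated correlation (adjusted p = 0.28). The unfolded protein response lost it in 1 (0.061), the amino acid response in 1 (0.43), both with array 4 turned, and ribosomal proteins in 3 (0.061, 0.14 and 0.056). The required number of arrays, the robust fit and the array weights do not enter the set test, so these alternatives repeat its main result. Calls were also gained, 21 over 11 lists. Array 4 as deposited added melanocyte markers (0.019), autophagy (0.022) and mitosis (0.036), and the dye term 7 lists; with an estimated correlation the adjusted p-values were 0.45, 0.40 and 0.51, and 0.33 to 0.46 for the 7. No centring added p53 targets (0.00059), the BCL2 family (0.021), PPAR and LXR targets (0.021), NF-kB targets (6.9e-05) and TGF-beta targets (0.0021). HS9 arrays alone added oxidative phosphorylation (0.0052), ribosome biogenesis (0.012) and autophagy (0.014), HS11 arrays alone mitosis (0.036), and omitting array 3 or 5 ribosome biogenesis (0.021) or PPAR and LXR targets (0.049). With an estimated correlation none of the gained calls held (adjusted p = 0.33 to 0.77), and 0 lists passed in any alternative. Spot brightness was not used here, so what low signal limits is unknown.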

Other observations

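The fit of all 5 arrays with a dye term, which was chosen after seeing the data, covers genes measured on array 4. It separates treatment from dye only if that column was turned and array 4 differs from the others in nothing else. Neither is established, and if the column was not turned, the effect given is that of the dyes. The effect in this fit is the average of the mean of the 4 other arrays and the single value of array 4, so 1 array carries as much weight as the rest together. Of 9169 genes 12 passed limma's threshold, 11 negative and 1 positive. The lowest were EGR1 (-2.93), CCN2 (-2.70), PMAIP1 (-2.31) and SESN2 (-2.27), followed by ABL2 (-2.16), NUP88 (-2.15), RCAN1 (-2.09), ASNS (-2.08), ATF4 (-1.84), the amino acid transporter subunit SLC3A2 (-1.79) and the kinase STK17A (-1.55), with GID8 (1.67) on the positive side. The value of GID8 comes from array 4 (3.94), since its mean on the other arrays was -0.59. Array 4 is fitted exactly in this fit, so the p-values behind these calls rest on the spread of the other 4 arrays. They measure no variation of array 4.

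Melanocyte markers lay on the positive side in this fit (limma camera adjusted p = 0.00058, and 0.33 as adjusted p with an estimated correlation), with 8 of 14 members positive and MITF at 1.63, SOX10 at 0.79 and TYR at 0.99, none of which passed alone. Array 4 carried much of this: TYR had 2.32 there and -0.35 on the others, SOX10 1.23 and 0.34, MITF 2.29 and 0.98, and the list median was 0.46 and -0.03. Mitosis (adjusted p = 0.0020, 17 of 24 positive) and cholesterol synthesis (0.0045, 8 of 13 positive) lay on the same side, and TGF-beta targets (0.0045, 13 of 19 negative), autophagy (0.011), NF-kB targets (0.012) and ribosome biogenesis (0.036) on the other. With an estimated correlation these adjusted p-values were 0.46, 0.46, 0.33, 0.37, 0.41 and 0.33. In the fit of the 4 arrays none of these lists passed, and the difference between the fits was not tested.

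With array 4 added as deposited and no dye term, a setting chosen before the data were examined, 54 genes passed (limma), all on the negative side. Melanocyte markers on the positive side (limma camera adjusted p = 0.019), autophagy on the negative (0.022) and mitosis on the positive (0.036) passed as sets there, and not with an estimated correlation (adjusted p = 0.45, 0.40 and 0.51 with an estimated correlation). Beside those described above, they included CCN1 (-2.24), EGFR (-1.77), the membrane-binding protein ANXA1 (-1.76), VEGFA (-1.46), NFKB2 (-1.38), AEN (-1.30), FOSL2 (-1.27), the amino acid transporter SLC7A5 (-1.21), THBS1 (-1.09), PDIA4 (-1.02) and the mitochondrial protease LONP1 (-0.93). These examples were chosen after their values had been seen.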
